A study of Rattus norvegicus with 4 samples.

How the data were processed

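Cardiomyocytes were isolated from the ventricles of Sprague-Dawley rats aged 1 to 2 days, plated for 24 h in medium with 10% serum, infected, and kept for 24 h in serum-free medium, per the labels' protocols. Total RNA was extracted with TRIzol, and 5 µg per sample was labelled with biotin for Affymetrix arrays. The samples fell into Ad-GFP and Ad-β-catenin-GFP, with replicates 1 and 2 in each, taken from the sample titles.

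The deposited value table held log2 expression values of 31099 probe sets for each of the 4 arrays. They were made with RMA, per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises the probes of a probe set. Its version, software and any filter are not given in the sources used here. The values ran from 1.77 to 13.99, and the quartiles of the 4 arrays were nearly equal. The table carries no detection call, so a low value cannot be told from background. A second deposited table held log2 values of 620 probe sets in 2 columns per virus, close to but not equal to those of the value table. How the authors normalized it is not given in the sources used here. Its column names gave the virus but not the replicate, so it served only to describe which probe sets the authors had selected.

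The 57 control probe sets were left out and 31042 were tested. Gene names came from the platform annotation, with symbols updated through gene identifiers to the rat reference gene table of assembly GRCr8, which matched 20758 of the 20826 probe sets with exactly 1 symbol. A further 436 probe sets had several symbols and 9780 had none, and these were named by probe set only. No genome coordinates are given, because the values carry no genome build.

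Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intercept and the virus as terms), adjusted by the Benjamini-Hochberg method over the 31042 probe sets and called at an adjusted p under 0.05. The fit had 2 residual and 2.79 prior degrees of freedom, and the median log2 difference over all probe sets was -0.03. Differences are Ad-β-catenin-GFP minus Ad-GFP. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 24 lists. Each list median was later also set against 10000 random lists drawn from the same 50 bins of mean expression. Each of 14217 genes entered by 1 probe set, that with the highest mean over the 4 arrays. Members of a list were also adjusted over the list alone with the p-values of limma. This was done for each of the 24 lists without a correction across lists. For such a member, rose or fell means by that test only. The lists were Wnt/β-catenin targets, Wnt pathway components, fetal and hypertrophic genes, sarcomere genes, calcium handling and ion channel genes, cardiac transcription factors, fatty acid oxidation, oxidative phosphorylation, glycolysis, cell cycle, fibroblast and matrix genes, endothelial, smooth muscle and pericyte, and leukocyte markers, interferon-response, NF-κB and inflammatory, unfolded protein and integrated stress response, heat shock, immediate-early and p53 target genes, cholesterol and lipid synthesis, cell junction, TGF-β and BMP response and Notch pathway genes.

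The tests, the lists and the rule for named genes were fixed before the data were examined. The rule took Ctnnb1, then on each side the 12 named genes with the largest difference among those called with non-overlapping groups. Where fewer than 12 passed, it filled the side in order of moderated p from named genes with non-overlapping groups and a difference of at least 1, by the brightest probe set of a gene. It then took up to 4 members of each list in order of moderated p. Symbols beginning with LOC or RGD were skipped in the first part. The members that passed when adjusted over a list alone are named as well, and so are the called probe sets.

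Alternatives fixed in advance were leaving out dim probe sets (a mean log2 under 5, or the dimmer 50%), quantile normalization, centring arrays on their medians, eBayes with an intensity trend and with a robust prior, a replicate block, leaving out each array in turn, a minimum log2 difference of 1, the mean over all probe sets of a gene, and the estimated correlation. Cyclic loess and array weights were added after the data were seen. The scripts were tested on simulated data with the real probe-set means and the fitted spread. In simulated arrays, 2 against 2 over 31042 probe sets, limma called 1.49% of probe sets changed by 1 on the log2 scale, 80.6% of those changed by 2 and 97% of those changed by 4. It called 4 unchanged probe sets, and 5.01% of unchanged probe sets had an unadjusted p under 0.05. On the real arrays, 38 probe sets differed by at least 2, and 2 of these were called. Their median SE was 0.385, against 0.152 over all probe sets, so the simulated shares do not describe large differences here. In independent simulated genes, camera called 0 of 23 lists that were not shifted. Those genes did not move together, so this does not show how often the preset correlation gives false calls on the real lists. There the estimated correlation ran from -0.0103 for smooth muscle and pericyte markers to 0.904 for oxidative phosphorylation genes.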

Results

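Gene expression was measured in ventricular cardiomyocytes of newborn Sprague-Dawley rats infected with one of 2 adenoviruses. The control virus, Ad-GFP, carries green fluorescent protein, and the other, Ad-β-catenin-GFP, carries β-catenin. β-catenin is a protein of cell junctions and the transcriptional coactivator of canonical Wnt signalling. RNA was taken 24 h after infection and hybridised to Affymetrix rat arrays, with 2 arrays per virus. The comparison of the viruses asks how β-catenin alters gene expression across the genome in primary cardiomyocytes. The values were log2 expression values of 31042 probe sets, and the median of an array lay between 5.49 and 5.50. The number of arrays limits the precision of every value below. The replicates are labelled biological, but the labels do not say that each came from a separate preparation of cells, so p-values measure the spread between these samples.

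Ctnnb1, the gene that encodes β-catenin, was read by 4 probe sets, and they did not move together. The probe set 1369733_at measured 8.23 ± 0.04 with Ad-GFP and 10.61 ± 0.55 with Ad-β-catenin-GFP (mean log2 ± SD, n = 2), a difference of 2.38 (SE 0.28) or 5.21-fold. Both β-catenin arrays lay above both control arrays, by 1.99 and 2.77 over the control mean for replicates 1 and 2. Ctnnb1 1375284_at, a dim probe set, measured 3.81 ± 0.19 and 4.59 ± 0.33. The brighter probe sets 1373067_at and 1373470_at differed by 0.00 (95% limits -0.33 to 0.34) and 0.06 (95% limits -0.29 to 0.42). The sign of the 1373067_at difference turned under quantile normalization (-0.04) and cyclic loess (-0.04, chosen after the data were seen), and without Ad-GFP replicate 2 (-0.05) or Ad-β-catenin-GFP replicate 2 (-0.05). That of 1373470_at turned without Ad-β-catenin-GFP replicate 2 (-0.04). None of the 4 probe sets passed the adjustment over all probe sets in limma, and the adjusted p of 1369733_at was 0.326. The labels give neither the species nor the span of the β-catenin sequence in the virus, so a probe set outside that span cannot check the infection.

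Known targets of Wnt/β-catenin signalling rose on the Ad-β-catenin-GFP arrays. Of the 35 targets measured, 10 rose and 2 fell when adjusted over the list alone, and 23 did not pass, while 0 passed the adjustment over all probe sets. Axin2, a negative feedback regulator of the pathway, rose from 4.31 ± 0.39 to 8.31 ± 0.14 (log2, n = 2), a nominal 16.0-fold. Its level with Ad-GFP cannot be told from background. Tnfrsf19, a receptor of the tumour necrosis factor family, rose by 2.30 (SE 0.14) from 3.86 with Ad-GFP, which cannot be told from background either. Lef1 and Tcf7, transcription factors that bind β-catenin, rose by 1.33 and 1.09. The inhibitors Znrf3, Wif1, Apcdd1 and Nkd1, which act at several steps of the pathway, rose by 1.23, 0.55, 0.50 and 0.45, and the homeobox genes Msx2 and Irx3 rose by 1.63 and 0.88. The cyclin gene Ccnd1 fell by 0.77 and Rspo3, which encodes a secreted Wnt agonist, fell by 1.10, both adjusted over the list alone.

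**Figure D1:**
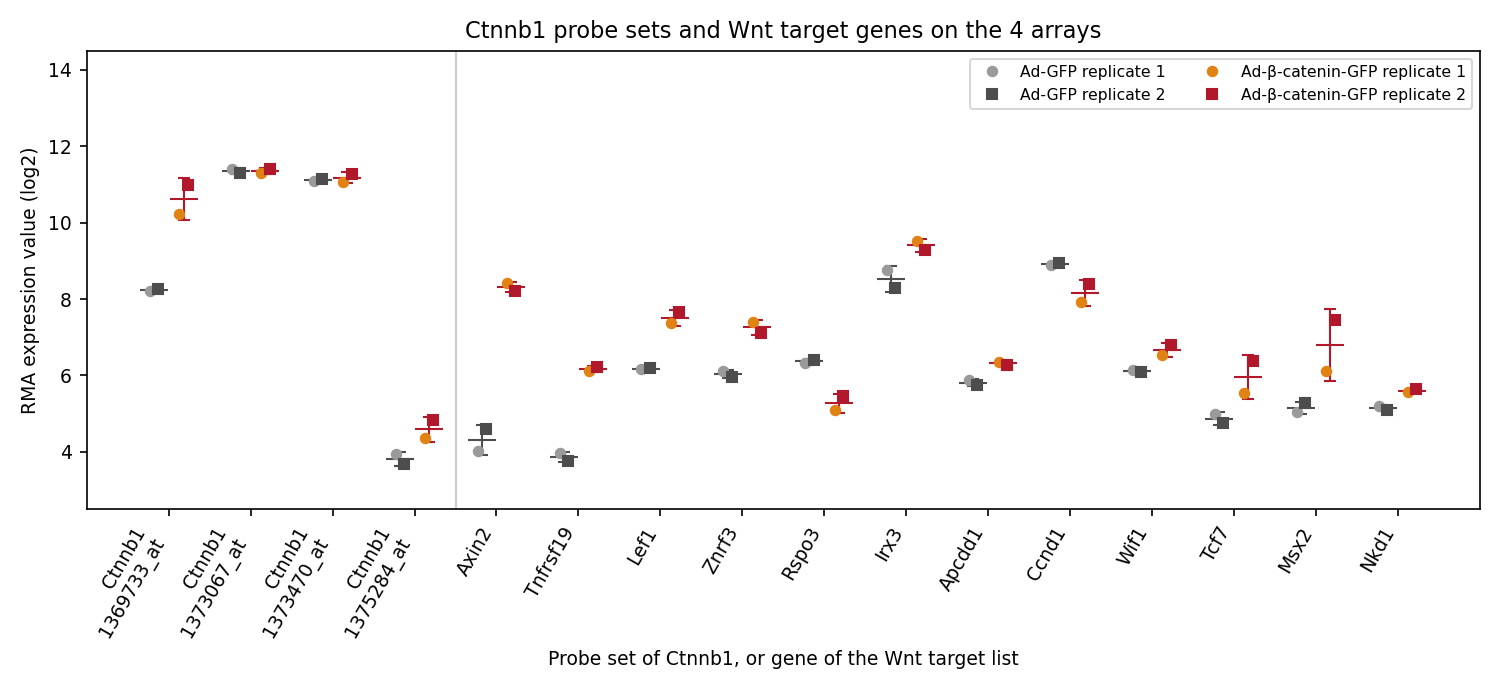
RMA expression values (log2, y axis) of the 4 Ctnnb1 probe sets and of the 12 Wnt target genes that passed when adjusted over the list alone (x axis), with 1 point per array and a horizontal mark and bar for the group mean and SD (n = 2). Ctnnb1 1369733_at and Axin2 stand 5.21-fold and a nominal 16.0-fold higher with Ad-β-catenin-GFP, while Ctnnb1 1373067_at and 1373470_at overlap between the groups.

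The Wnt target list as a whole rose, with a median difference of 0.26 and 24 of 35 members higher (camera, limma, adjusted p = 0.0026). The adjusted p was 0.695 with an estimated correlation. The call was also lost among the brighter 50% of probe sets (adjusted p = 0.0663) and without Ad-β-catenin-GFP replicate 2 (median 0.08, adjusted p = 0.0987). The components of the pathway, such as Wnt ligands, Frizzled receptors and the destruction complex, did not pass as a list (49 measured, 33 lower, median -0.09, camera adjusted p = 0.303). Within it, the receptor gene Fzd1 rose by 1.01 and Gsk3b, a kinase that marks β-catenin for degradation, fell by 1.38 when adjusted over the list alone. Wnt4 and Dkk3, which differed by -0.82 and 0.83, did not pass.

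Across all 31042 probe sets, 2 passed an adjusted p of 0.05 in limma, both higher with Ad-β-catenin-GFP and both without a gene name here. Probe set 1390429_at went from 3.49 ± 0.25, which cannot be told from background, to 8.45 ± 0.08, a nominal 31.2-fold rise. Probe set 1377161_at went from 5.02 ± 0.03 to 8.35 ± 0.01, a 10.0-fold rise (log2 mean ± SD, n = 2, limma adjusted p = 0.0252 for each). With a replicate block neither passed (adjusted p = 0.344 for each). Axin2 missed that threshold (adjusted p = 0.144) and passed it when dim probe sets were left out, at 0.0413 with a mean log2 of at least 5 and 0.0343 in the brighter 50%. Without a filter, its adjusted p ranged from 0.0778 to 0.897 over the alternatives. An unadjusted p under 0.05 was found for 3490 probe sets, 1778 higher and 1712 lower, where chance gives 1552. The difference was at least 1 on the log2 scale for 602 probe sets, 390 higher and 212 lower. The groups did not overlap for 43.9% of probe sets, against 33.3% by chance. No probe set passed when any 1 array was left out, and the number with an unadjusted p under 0.05 then became 1439 without Ad-GFP replicate 1, 1427 without Ad-GFP replicate 2, 2644 without Ad-β-catenin-GFP replicate 1 and 5961 without Ad-β-catenin-GFP replicate 2.

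Among named genes with both groups apart and a difference of at least 1, 12 higher and 12 lower ones were taken in order of moderated p, since no named gene passed over all probe sets. They are not the genes with the largest differences. Krt19 differed by 4.02 and Il6 by -3.03, and neither is among them. After Axin2 and Tnfrsf19, the genes on the higher side were Vsnl1, a neuronal calcium sensor gene, at 2.86 ± 0.02 against 5.36 ± 0.35, and the transcription factor gene Mycn, at 7.11 ± 0.06 against 9.26 ± 0.28. The growth factor gene Igf1 measured 5.28 ± 0.07 and 6.85 ± 0.16. Rab27a, which encodes a small GTPase of secretory vesicles, differed by 2.52. Popdc3, of a family of membrane proteins of striated muscle, differed by 2.08, and the integrin gene Itga9 by 1.95, although a second Itga9 probe set, 1385255_at, differed by 0.08. Lbh, Wipf3, the imprinted gene Mest and the small heat shock protein gene Hspb7 differed by 1.38, 1.24, 1.17 and 1.12. Axin2, Tnfrsf19, Vsnl1 and Rab27a had means under 5 with Ad-GFP, near background, so the sizes of their differences are nominal. The adjusted p of the 12 lay between 0.144 and 0.323.

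On the lower side, Foxa2, a forkhead transcription factor gene, measured 5.78 ± 0.15 with Ad-GFP and 3.40 ± 0.24 with Ad-β-catenin-GFP. Adra2a, the gene of the α2A-adrenergic receptor, measured 5.58 ± 0.05 and 3.85 ± 0.02. Ckmt1, the gene of a mitochondrial creatine kinase, differed by -2.07, Rhpn2 by -1.83 and Rab6b, a GTPase gene of the Golgi, by -1.53. The phosphatase gene Dusp14, Tent5b and the integrin gene Itga3 differed by -1.32, -1.24 and -1.16. Hr, Crym, Cyfip2 and Bclaf3 differed by -1.13, -1.11, -1.05 and -1.03. Foxa2, Adra2a, Rhpn2, Rab6b and Cyfip2 had means under 5 with Ad-β-catenin-GFP, near background, so the sizes of their differences are nominal. The adjusted p of these 12 lay between 0.238 and 0.34.

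**Figure D2:**
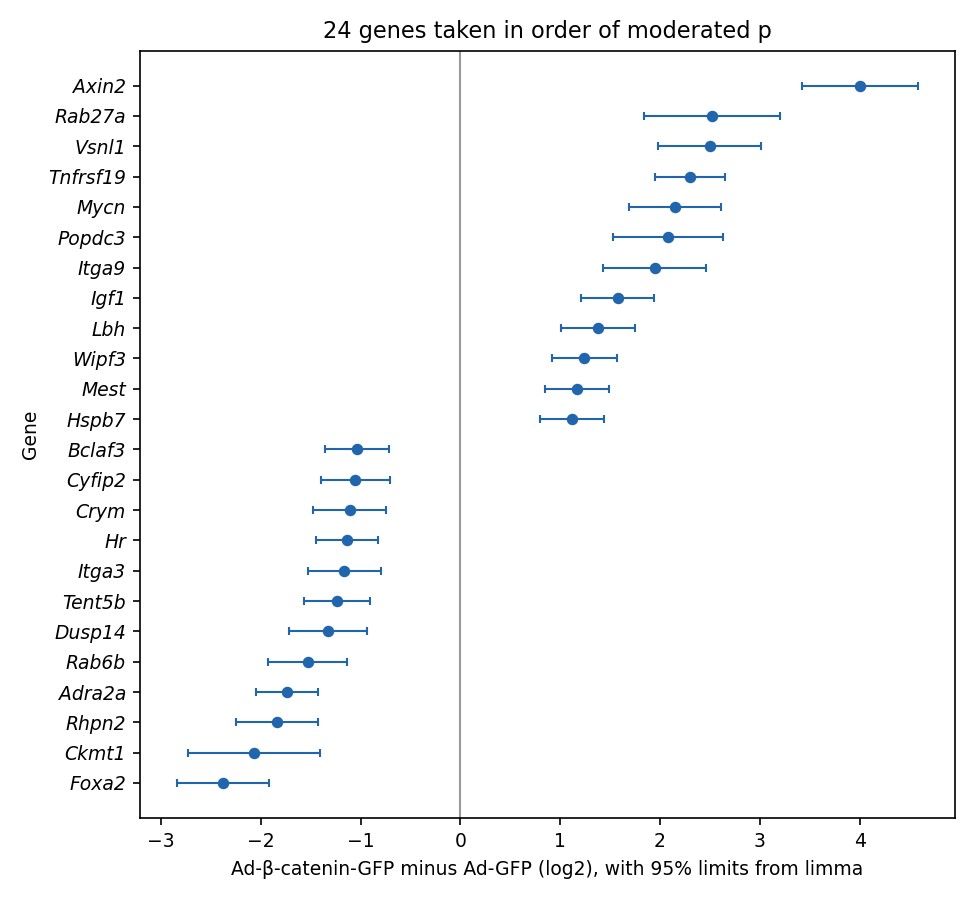
Difference between the groups (Ad-β-catenin-GFP minus Ad-GFP, log2, x axis) for 24 named genes (y axis), taken in order of moderated p and not by size, with 1 point per gene and bars for the 95% limits from limma (n = 2 per group). The values run from -2.38 for Foxa2 to a nominal 16.0-fold difference for Axin2, and no gene passed the adjustment over all probe sets.

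Genes of the sarcomere, the contractile unit of muscle, rose as a list (33 measured, median 0.35, camera adjusted p = 1.11e-04), with 12 members up and 1 down when adjusted over the list alone and 20 that did not pass. The adjusted p was 0.695 with an estimated correlation, as it was for each of the other 16 lists called. Myl7, the atrial regulatory light chain gene, rose by 1.52 (SE 0.18), and Myom2, which encodes an M-band protein, rose from 6.56 ± 0.59 to 8.43 ± 0.05. Myl2 and Myh7, the ventricular regulatory light chain and β-myosin heavy chain genes, each rose by 0.63, and Myoz2 rose by 0.84. Tnni3, Tnni1, Myom1, Ldb3, Fhod3, Smpx and Ttn also rose, and Des, the desmin gene, fell by 0.45. The sarcomere median was 0.52 without Ad-GFP replicate 1 and 0.21 without Ad-GFP replicate 2, and both kept the call.

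Calcium handling and ion channel genes also rose as a list (44 measured, 31 higher, median 0.29, camera adjusted p = 6.61e-04, and adjusted p = 0.695 with an estimated correlation). No member passed when adjusted over the list alone. The potassium channel genes Kcnh2 and Kcnq1 differed by 1.32 and 0.91. Atp2a2, the calcium pump gene of the sarcoplasmic reticulum, and Pln, the gene of its inhibitor phospholamban, differed by 0.99 and 0.95 at their brightest probe sets. Other Atp2a2 probe sets ranged from -0.10 (1375164_at, dim) to 1.25 (1398862_at). The list median was 0.15 without Ad-β-catenin-GFP replicate 1 and kept its call. Cardiac transcription factors rose as a list too (26 measured, 16 higher, median 0.25, camera adjusted p = 0.0275, and adjusted p = 0.695 with an estimated correlation), with 0 members passing over the list alone. Tbx5, Hand2 and Mef2a differed by 1.41, 0.90 and 0.57, and Tead1 by -0.71. This call was lost without Ad-GFP replicate 2 (median 0.02, adjusted p = 0.297) and without Ad-β-catenin-GFP replicate 2 (0.20, adjusted p = 0.067), and the median was 0.14 without Ad-β-catenin-GFP replicate 1.

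Fetal and hypertrophic genes fell as a list (25 measured, 18 lower, median -0.30, camera adjusted p = 0.0414, and adjusted p = 0.695 with an estimated correlation). The list holds genes re-expressed in the stressed adult heart beside general stress genes such as Hmox1 and Egr1. The natriuretic peptide genes Nppa and Nppb differed by -0.21 and -0.36 and did not pass. Acta1, the skeletal α-actin gene, fell by 0.81 and Ankrd23, which encodes an ankyrin repeat protein of muscle, fell by 0.99 when adjusted over the list alone. Hspb7 and Myh7, which the list also holds, rose by 1.12 and 0.63 by the same test, and 21 members did not pass. The call was lost without Ad-β-catenin-GFP replicate 1 (median -0.06, adjusted p = 0.778), without Ad-GFP replicate 1 (-0.30, adjusted p = 0.136), when dim probe sets were left out and when the probe sets of a gene were averaged.

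Genes of oxidative phosphorylation, the respiratory chain and ATP synthase of mitochondria, were higher in all 54 members measured, and the groups did not overlap for 52 of them. The list rose by a median of 0.56 (camera adjusted p = 1.04e-20, and adjusted p = 0.695 with an estimated correlation, which was 0.904 for these genes). No member passed when adjusted over the list alone. Cox8b, a subunit gene of cytochrome c oxidase, measured 7.39 ± 0.13 and 9.53 ± 0.78, and Ndufs1, Ndufc2 and Atp5pf differed by 0.71, 0.77 and 0.79. Fatty acid oxidation genes rose as a list as well (38 measured, 33 higher, median 0.54, camera adjusted p = 3.19e-06, and adjusted p = 0.695 with an estimated correlation), again with 0 members passing over the list alone. Ppargc1a, the gene of a coactivator of mitochondrial biogenesis, differed by 1.47, and Hadh, Etfdh and the fatty acid binding protein gene Fabp3 by 1.44, 1.31 and 0.75.

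Both mitochondrial lists stood higher on Ad-β-catenin-GFP replicate 1 than on replicate 2. The median above the Ad-GFP mean was 0.76 and 0.32 for oxidative phosphorylation genes and 0.94 and 0.10 for fatty acid oxidation genes, which are also the medians without the other replicate, and each kept its call. Leukocyte markers stood apart on the same array, at 0.86 and 0.03. Glycolysis genes rose as a list (29 measured, 19 higher, median 0.19, camera adjusted p = 0.00856, and adjusted p = 0.695 with an estimated correlation). Aldoc and Pdk1, the genes of an aldolase and of a kinase that inhibits pyruvate dehydrogenase, rose by 1.16 and 0.73 when adjusted over the list alone, and 27 members did not pass. Pfkm and Pfkfb2 differed by 1.21 and 0.47. The glycolysis median was 0.01 without Ad-GFP replicate 1, where the call was lost (adjusted p = 0.283), and 0.10 without Ad-β-catenin-GFP replicate 1. It was also lost in the brighter 50% of probe sets. Cholesterol and lipid synthesis genes did not pass as a list (34 measured, 25 lower, median -0.16, camera adjusted p = 0.0542, and adjusted p = 0.695 with an estimated correlation), and Elovl6, Fads2, Sc5d and Ggps1 differed by -0.88, -0.66, -0.58 and -0.56. They passed downward under 8 other alternatives, among them quantile normalization, a replicate block and both filters on dim probe sets, with adjusted p from 8.97e-04 without Ad-β-catenin-GFP replicate 2 to 0.0476 with array weights (chosen after the data were seen). Without Ad-GFP replicate 1 the adjusted p was 0.00291, and without Ad-β-catenin-GFP replicate 1 the median was 0.04 (adjusted p = 0.778).

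Cell cycle genes rose as a list (70 measured, 51 higher, median 0.27, camera adjusted p = 6.17e-05, and adjusted p = 0.695 with an estimated correlation). Ccnd2, the cyclin D2 gene, rose from 9.69 ± 0.31 to 11.29 ± 0.09 and Stmn1, the gene of a microtubule regulator, rose from 8.93 ± 0.18 to 10.43 ± 0.21 when adjusted over the list alone, and 68 members did not pass. Racgap1 and Mad2l1, which act in mitosis, differed by 1.35 and 0.85. The list median was 0.62 on Ad-β-catenin-GFP replicate 2 and 0.05 on replicate 1, and with replicate 1 alone the call was lost (adjusted p = 0.573). Endothelial markers stood apart on the same replicate 2, at 1.01 against -0.04.

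Target genes of p53, the DNA damage response factor, fell as a list (25 measured, 20 lower, median -0.40, camera adjusted p = 6.61e-04, and adjusted p = 0.695 with an estimated correlation), with 0 members passing over the list alone. The apoptosis genes Apaf1 and Fas and the phosphatase gene Ptpn14 differed by -0.59, -0.52 and -0.62, and Ei24 by 0.76. Heat shock genes rose as a list (23 measured, 19 higher, median 0.15, camera adjusted p = 0.0201, and adjusted p = 0.695 with an estimated correlation). The small heat shock protein gene Hspb6 rose by 0.99 and Hspa2 fell from 7.67 ± 0.33 to 6.17 ± 0.14 when adjusted over the list alone, and 21 members did not pass, among them Hspb1 and Ahsa1, at 0.57 and 0.56. The heat shock call was lost without Ad-GFP replicate 2 (median 0.17, adjusted p = 0.0953) and without Ad-β-catenin-GFP replicate 2 (0.04, adjusted p = 0.985), where the test turned downward. Its median was 0.46 without Ad-β-catenin-GFP replicate 1 and 0.26 without Ad-GFP replicate 1. The call was also lost under quantile normalization, cyclic loess and both filters on dim probe sets. Its median lay inside the central 95% of 10000 random lists matched on mean expression (upper bound 0.193), while those of the other 16 lists called lay outside theirs. So did lists that were not called, cholesterol and lipid synthesis (-0.161, lower bound -0.105) and TGF-β and BMP response (-0.213, lower bound -0.104). Genes drawn at random do not move together as list members do, so the random range is too narrow and lying outside it does not support a call. The unfolded protein and integrated stress response list did not pass (45 measured, 24 lower, median -0.04, camera adjusted p = 0.705, and adjusted p = 0.948 with an estimated correlation), with Slc7a5, Ppp1r15a, Cebpb and Pdia4 at -0.94, -0.83, -0.71 and 0.78. It passed in opposite directions on the Ad-β-catenin-GFP arrays, upward without replicate 1 (median 0.29, adjusted p = 6.00e-04) and downward without replicate 2 (median -0.31, adjusted p = 3.02e-05).

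Targets of NF-κB and other inflammatory genes fell as a list (49 measured, 40 lower, median -0.37, camera adjusted p = 2.49e-06, and adjusted p = 0.695 with an estimated correlation). Adjusted over the list alone, 8 members fell, 0 rose and 41 did not pass. The cytokine gene Il6 went from 9.66 ± 0.61 to 6.62 ± 0.52 and Csf2 from 8.44 ± 0.69 to 5.55 ± 1.21, although a second and dim Csf2 probe set, 1371227_at, differed by -0.21. Ptgs2, the gene of inducible cyclooxygenase, fell by 2.44 (SE 0.51). The chemokine genes Ccl20, Cxcl3 and Ccl7 fell by 1.36, 1.20 and 0.89, the cytokine gene Lif by 1.01 and Tnfaip3, an inhibitor of NF-κB signalling, by 0.90. The Ad-GFP arrays differed from each other in this list, with medians of -0.30 and 0.30 around their mean, and without Ad-GFP replicate 2 the list median was -0.17 and kept its call. Interferon-response genes did not pass as a list (48 measured, 30 lower, median -0.07, camera adjusted p = 0.297, and adjusted p = 0.853 with an estimated correlation), and Bst2, Oasl, Psmb8 and Tap2 differed by -0.85, -0.63, -0.45 and -0.36. The Ad-GFP arrays lay at -0.27 and 0.27 in it. The list passed downward without Ad-GFP replicate 1 (median -0.35, adjusted p = 2.13e-08) and upward without Ad-GFP replicate 2 (median 0.17, adjusted p = 0.00154).

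Immediate-early genes, which respond within minutes to growth factors and stress, fell as a list (33 measured, 27 lower, median -0.42, camera adjusted p = 6.61e-04, and adjusted p = 0.695 with an estimated correlation), with 0 members passing over the list alone. Klf2, Zfp36 and Junb differed by -1.04, -0.49 and -0.44, and Egr2 by 0.84, although the other 4 Klf2 probe sets ranged from -1.04 to 0.05. The call was lost without Ad-β-catenin-GFP replicate 1 (median -0.13, adjusted p = 0.392). Cell junction genes fell as a list (39 measured, 30 lower, median -0.16, camera adjusted p = 0.0144, and adjusted p = 0.695 with an estimated correlation), also with 0 members passing over the list alone. Afdn, Cdh3 and Ocln differed by -0.67, -0.62 and -0.60, and Cdh2, the N-cadherin gene, by 0.52. That call was lost without Ad-GFP replicate 2 (-0.15, adjusted p = 0.0543), without Ad-β-catenin-GFP replicate 1 (-0.13, adjusted p = 0.0846) and when dim probe sets were left out. Neither TGF-β and BMP response genes (41 measured, 27 lower, median -0.21, camera adjusted p = 0.303) nor Notch pathway genes (27 measured, 15 lower, median -0.05, camera adjusted p = 0.44) passed as a list. Without Ad-β-catenin-GFP replicate 2 the TGF-β and BMP list passed downward (median -0.44, adjusted p = 3.80e-04), and without replicate 1 it turned upward (median 0.06, adjusted p = 0.133). Its adjusted p over all arrays was 0.835 with an estimated correlation. Bambi, Smad9, Nbl1 and Tgfb3 differed by 0.64, 0.50, -0.63 and -0.64, and Maml2, Numb, Maml1 and Adam10 by -0.47, -0.31, -0.29 and 0.39.

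Markers of other cell types of the heart were measured beside these groups. Fibroblast and matrix genes rose as a list (48 measured, 35 higher, median 0.29, camera adjusted p = 0.00123, and adjusted p = 0.695 with an estimated correlation). The collagen gene Col6a3 rose by 1.10 and the matrix protease gene Mmp3 fell by 2.37 when adjusted over the list alone, and 46 members did not pass, among them Col3a1 and Col6a2, at 0.75 and 0.55. The fibroblast call was lost without Ad-GFP replicate 1 (0.14, adjusted p = 0.0854) and without Ad-β-catenin-GFP replicate 2 (0.15, adjusted p = 0.2), and the median was 0.46 without Ad-GFP replicate 2. Leukocyte markers rose as a list (27 measured, 22 higher, median 0.38, camera adjusted p = 6.61e-04, and adjusted p = 0.695 with an estimated correlation). The actin-bundling gene Lcp1 rose by 1.12 when adjusted over the list alone and 26 members did not pass, among them Tyrobp, Cd74 and Mrc1, at 0.79, 0.72 and 0.66. Without Ad-β-catenin-GFP replicate 1 the leukocyte median was 0.03 (adjusted p = 0.526), and without replicate 2 of that group it was 0.86. Endothelial markers rose as a list (24 measured, 19 higher, median 0.50, camera adjusted p = 0.00972, and adjusted p = 0.695 with an estimated correlation), with 0 members passing over the list alone and Emcn, Cldn5, Podxl and Tek at 1.67, 1.12, 0.73 and -0.33. The endothelial median was 1.01 without Ad-β-catenin-GFP replicate 1 and -0.04 without replicate 2, where the test turned downward (adjusted p = 0.583). It was 0.22 without Ad-GFP replicate 1, where the call was lost (adjusted p = 0.206), and 0.77 without Ad-GFP replicate 2. Smooth muscle and pericyte markers did not pass (17 measured, 9 higher, median 0.04, camera adjusted p = 0.44), with Rgs5, Myh11, Cspg4 and Cnn1 at 0.98, 0.40, -0.50 and -1.21.

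**Figure D3:**
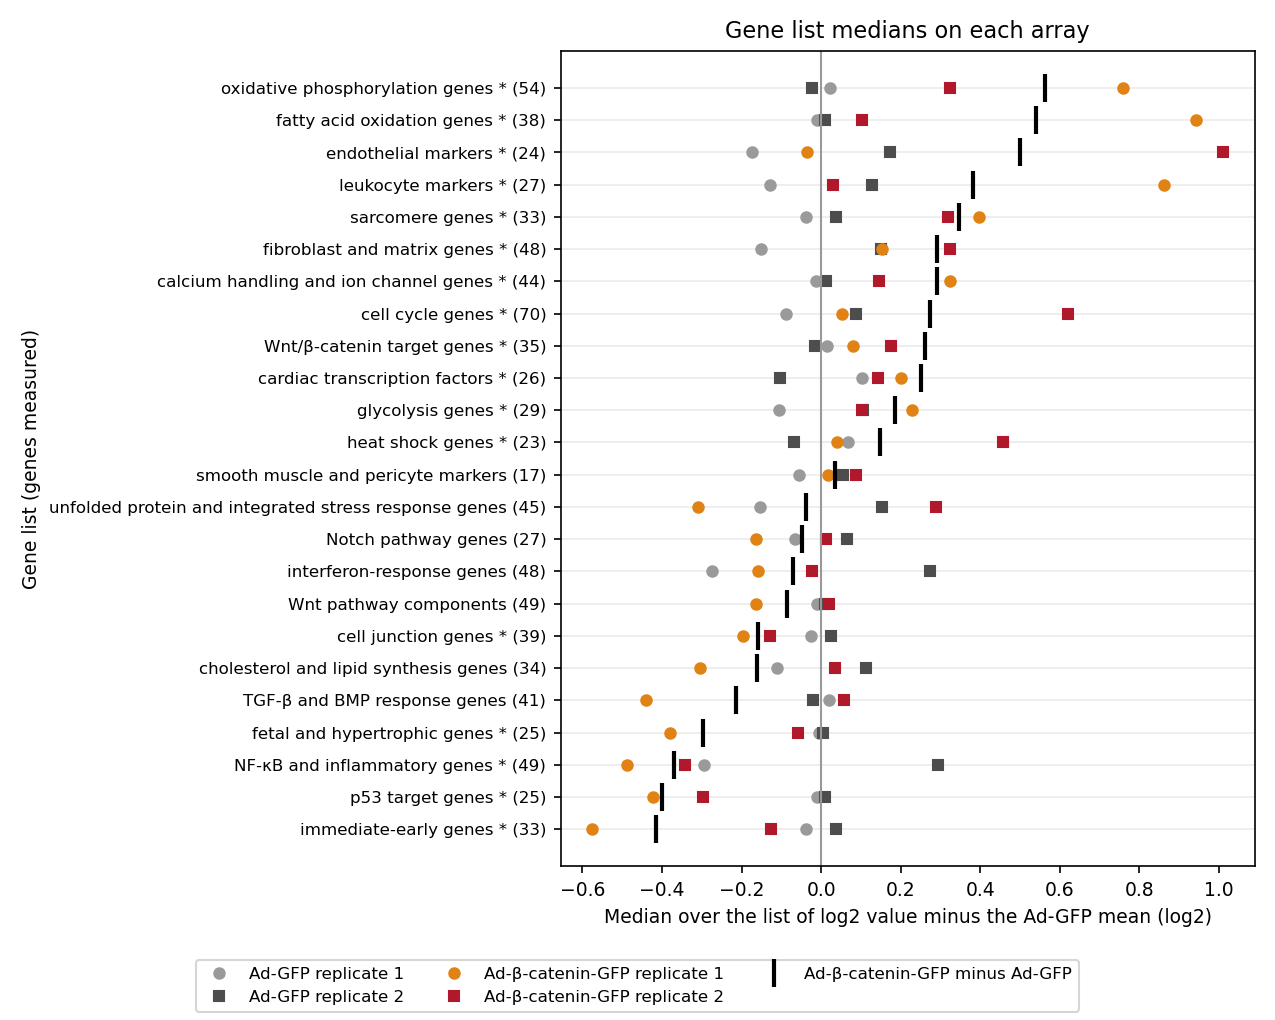
Median over each gene list (y axis, with the number of genes measured) of the log2 value minus the Ad-GFP mean of the same gene (x axis, log2), with 1 point per array, a black mark for the median difference between the groups and an asterisk for a camera adjusted p under 0.05 at the preset correlation. The points of the Ad-GFP arrays mirror each other because they are set against their own mean, and the Ad-β-catenin-GFP arrays lie at 0.94 and 0.10 for fatty acid oxidation genes but at 0.40 and 0.32 for sarcomere genes.

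In all, 17 of the 24 lists passed camera at the preset correlation, 12 upward and 5 downward, and 0 passed with an estimated correlation. The repeated 0.695 is 1 value tied by the adjustment, over lists with unadjusted camera p from 0.147 to 0.579. With 2 residual degrees of freedom that test has little power. The oxidative phosphorylation list, with all 54 members higher, had an unadjusted camera p of 0.229. At its estimated correlation of 0.904 the members move nearly together, so their shared direction does not show that this p is too large. At the preset correlation, camera p-values are too small where the genes of a list move together more than that value assumes. How often this gave false calls was not tested. Members that passed over a list alone were not corrected for the 24 lists, and 0 list members passed over all probe sets. The values of list members are those of the brightest probe set of a gene. Not all genes named were checked for this, and Tnni3, Ttn, Lif, Vim, Sparc, Cd48, Tnnt2 and Myh6 are among those left out. Besides Ctnnb1, of 61 checked genes that have several probe sets, 32 had a dimmer one that differed by under 50% as much or in the other direction. For 14 of them, Apaf1, Atp2a2, Cdh2, Col6a2, Ggps1, Hand2, Klf2, Mad2l1, Maml2, Numb, Pfkm, Ptpn14, Rspo3 and Wipf3, that probe set had a mean log2 of at least 5. The Ad-GFP arrays were closer to each other than any pair across viruses, while the Ad-β-catenin-GFP arrays differed more than Ad-β-catenin-GFP replicate 2 did from either Ad-GFP array. Across probe sets, which are not independent replicates, Pearson's r was 0.992 between the Ad-GFP arrays and 0.985 between the Ad-β-catenin-GFP arrays. It was 0.977 and 0.975 between Ad-β-catenin-GFP replicate 1 and Ad-GFP replicates 1 and 2, and 0.987 and 0.988 for Ad-β-catenin-GFP replicate 2. The values lay at least 1 apart for 900 probe sets between the Ad-β-catenin-GFP arrays and for 178 between the Ad-GFP arrays. The first principal component held 62.2% of the variance, with scores of 53.2 and 4.91 for Ad-β-catenin-GFP replicates 1 and 2, and -26.2 and -32 for Ad-GFP replicates 1 and 2.

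A second deposited table gave the authors' own selection of 620 probe sets with values for 2 arrays of each virus, 403 higher and 217 lower with β-catenin, each by at least 1 on the log2 scale. This list was chosen on these samples, so its directions are not independent evidence. All 620 had the same direction in the value table, 558 of them with a difference of at least 1, 501 with an unadjusted p under 0.05 and 2 with an adjusted p under 0.05 in limma. The differences of the tables had a Pearson's r of 0.998 across the 620 probe sets and lay a median of 0.0428 apart. Of the Wnt targets, 7 were among the higher and 1 among the lower probe sets of that table, and of the inflammatory genes 0 and 10. It held 11 cell cycle genes, 8 calcium handling and ion channel genes and 5 sarcomere genes, all among the higher, and 0 interferon-response genes. Also among the higher were 5 fatty acid oxidation, 5 endothelial and 3 leukocyte genes, but only 1 of the 54 oxidative phosphorylation genes measured.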

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

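Cyclic loess and array weights were chosen only after the results were seen. The 2 called probe sets kept their calls under every normalization, filter, prior, minimum difference and array weighting tried. With a mean log2 of at least 5 and in the brighter 50% of probe sets, 3 were called, Axin2 being added. Leaving out any 1 array left 0 called, from lowest to highest 0 to 0, with 1427 to 5961 at an unadjusted p under 0.05. Such a fit assumes that the lone array of a virus varies like the arrays of the other virus, and it has fewer samples. Same-numbered arrays deviated from their group means with a correlation of 0.179, and no label says that a number marks a shared preparation. With a replicate block, 0 probe sets were called, 0 higher, against 3984 at an unadjusted p under 0.05, and 18 lists. The difference of Ctnnb1 1369733_at stayed between 1.99 and 2.77 without 1 array.

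With an estimated correlation 0 lists were called. The Wnt/β-catenin target list, at a median of 0.26, then had an adjusted p of 0.695. Its median was 0.424 with a mean log2 of at least 5 (camera adjusted p = 0.0109) and 0.26 in the brighter 50% of probe sets (adjusted p = 0.0663). Without 1 array its median ran from 0.08 to 0.228. Its adjusted p ran from 1.88e-05 to 0.0987 over those fits. Over all alternatives, 271 list results kept their side and direction, 43 lost the call in the same direction, 11 gained it and 11 turned. Of those that turned, endothelial and heat shock genes also lost the call, and interferon-response and unfolded protein genes (the latter without Ad-β-catenin-GFP replicate 1) gained one. Sarcomere, calcium handling and ion channel, fatty acid oxidation, oxidative phosphorylation, NF-κB and p53 target lists kept their calls under the 13 alternatives run for lists besides the estimated correlation. The robust prior and the minimum difference were not run for lists.

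The results that turned had these values. Ctnnb1 1373067_at was at -0.035 under quantile normalization and -0.042 under cyclic loess. Without 1 array it ran from -0.052 (Ad-GFP replicate 2) to 0.059, also turning without Ad-β-catenin-GFP replicate 2, and 1373470_at from -0.036 (Ad-β-catenin-GFP replicate 2) to 0.162. List medians without 1 array ran from -0.349 to 0.174 for interferon-response, -0.31 to 0.29 for unfolded protein, -0.163 to 0.012 for Notch, -0.163 to 0.019 for Wnt components, -0.305 to 0.035 for cholesterol, -0.441 to 0.058 for TGF-β and BMP, -0.035 to 1.011 for endothelial, 0.017 to 0.088 for smooth muscle and 0.04 to 0.457 for heat shock genes. The interferon list turned without Ad-GFP replicate 2, and the Wnt component, cholesterol and TGF-β lists without Ad-β-catenin-GFP replicate 1. The unfolded protein and Notch lists turned when either of these 2 arrays was left out, and the endothelial, smooth muscle and heat shock lists without Ad-β-catenin-GFP replicate 2. The camera direction opposed the sign of the median for Notch genes without Ad-GFP replicate 2 (-0.035) and for the last 2 lists at their lowest medians. Leaving out an array lowers the number of samples, and otherwise the cause was not tested. Dim probe sets lie near background, where RMA values give no detection limit.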

Other observations

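The genes in this paragraph and the next were chosen after their values were seen, and none passed the adjustment over all probe sets. Several, among them Rab27a, Sstr2 (1368782_at), Krt19 and Cxadr, had a group mean under 5, near background, so their sizes are nominal. Rab27a was read by 3 probe sets, which differed by 2.18, 2.52 and 2.84. The probe sets of Igf1 differed by 1.57, 1.57 and 0.68, and those of Ghr, the growth hormone receptor gene, by 1.46 and 0.76. The somatostatin receptor gene Sstr2 measured 3.32 ± 0.13 and 5.84 ± 0.31 (log2, n = 2) on 1368782_at, while its second probe set differed by 0.82. Krt19, a keratin gene, differed by 4.02 with an SE of 0.84, and G0s2, which encodes an inhibitor of lipolysis, by 3.08 with an SE of 0.36. Ckm, the muscle creatine kinase gene, differed by 1.72, Mb, the myoglobin gene, by 1.65 and Sspn, the sarcospan gene, by 0.48 to 1.93 on 5 probe sets. The 3 probe sets of Ppargc1a differed by 1.47, 1.69 and 1.78.

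On the lower side, Ptges, which encodes a prostaglandin E2 synthase, differed by -2.21 and -1.42, and Ptger3, which encodes a prostaglandin E2 receptor, by -1.88 and -0.80. The plasminogen activator inhibitor gene Serpinb2 measured 10.25 ± 0.92 and 7.51 ± 1.11. Tgfa, a ligand of the epidermal growth factor receptor, differed by -1.62 and -1.44, Klf5 by -1.49 to -0.33 on 4 probe sets, and Cxadr, the gene of the coxsackievirus and adenovirus receptor, by -1.59. Ad-β-catenin-GFP replicate 2 stood further above the controls than replicate 1 at Ctnnb1 1369733_at, by 2.77 against 1.99, but replicate 1 lay further from the control arrays over all probe sets. The endothelial genes Emcn and Cd93 (1368393_at) had SDs of 1.40 and 1.48 between the Ad-β-catenin-GFP arrays, and the macrophage genes Adgre1 and Fcer1g had SDs of 1.63 and 1.34.

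Of the tests below, only those of lists matched on mean expression were written before their result was seen. The Ctnnb1 probe sets disagreed, with a highest upper 95% limit of 1.33 among the other 3, that of a dim probe set, and a lower limit of 1.66 for 1369733_at. A signal ceiling of the array is argued against by the distance of 2.64 between 1373067_at and the brightest value, more than the 2.38 at 1369733_at, although only 4 probe sets about as bright were higher by at least 0.9, and saturation of its own probes was not tested. The gap of 2.32 between 1369733_at and 1373470_at may arise because the viral transcript lacks the sequence that the other probe sets read, which cannot be told apart here because the position of the probes was not examined.

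The mitochondrial lists lay outside lists of like brightness, with medians of 0.56 for oxidative phosphorylation and 0.54 for fatty acid oxidation against upper bounds of 0.126 and 0.126 of the central 95% of 10000 random lists each. These bounds speak to brightness only, because genes drawn at random do not move together as list members do. A larger share of cardiomyocytes would lower fibroblast and matrix genes. The 95% bootstrap interval of their median, over genes and not arrays, began at 0.131. The median stayed between 0.142 and 0.459 without 1 array. Vim and Sparc measured 12.14 and 12.05 with Ad-GFP and 12.27 and 12.10 with Ad-β-catenin-GFP, and 0 of the 48 genes are in another list. No fall was seen in this list, but its genes move together (estimated correlation 0.236). The interval therefore does not measure the spread between cultures, and a larger share cannot be excluded. Genes that cardiomyocytes express do not decide the question either. Of the 33 sarcomere genes, 23 were higher and 10 lower. Tnnt2, Tnnc1 and Actn2 differed by 0.085, -0.107 and 0.182 and Myh6 by 1.57 at their brightest probe sets, all looked up after the values were seen. The oxidative phosphorylation list kept its call and more than 50% of its median without Ad-β-catenin-GFP replicate 1 (0.324), so that array is not its only source. The fatty acid oxidation median without it was 0.102, and there the share of the single array cannot be told apart with 1 array left. A hypothesis that remains is that β-catenin may raise respiratory chain genes. A larger share of cardiomyocytes and a difference between the preparations of the arrays are left open.

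The fall of inflammatory genes lay outside lists of like brightness, where the central 95% of 10000 medians began at -0.092. Here too the bound speaks to brightness only. Fewer leukocytes would lower their markers. The 95% bootstrap interval of the leukocyte median, over genes and not arrays, began at 0.123 and, without any 1 array, no lower than -0.082. The markers had medians of 0.86 and 0.03 on the Ad-β-catenin-GFP arrays, and the brightest, Cd48, measured 8.57 and 8.61. No fall was seen, but the markers move together (estimated correlation 0.559). Some, such as Mrc1 and Tyrobp at 3.40 and 4.46 with Ad-GFP, lay too near background to show a fall. Fewer leukocytes therefore cannot be excluded. A weaker response to the virus cannot be told apart, since the interferon median was -0.07 with all arrays (95% bootstrap interval over genes -0.121 to 0.016) but -0.349 beside an inflammatory median of -0.542 without Ad-GFP replicate 1, and 0.174 without Ad-GFP replicate 2. Without Ad-GFP replicate 2 the inflammatory median was -0.174, less than 50% of its size, so the share due to that array cannot be told apart with 1 control array left. Lower inflammatory gene expression with β-catenin may remain as a hypothesis beside fewer leukocytes, a weaker response to the virus and a difference between the control cultures.

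The 4 arrays can be split into pairs in 3 ways, too few for a share under 0.05. The split by virus gave 3490 probe sets with an unadjusted p under 0.05 in limma, the only 1 of the 3 with as many. The highest of the others gave 1059. In those, any difference between the viruses enters the residual spread and lowers the count, so they do not show what chance would give.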
